A study of Mus musculus with 22 samples.

How the data were processed

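Polyadenylated RNA from whole mouse lung was sequenced in 22 libraries. The labels give a sex, an oxygen exposure (room air or hyperoxia) and a day of harvest (postnatal day 7, PND7, or postnatal day 21, PND21) for each library, which makes 8 groups of 2 or 3 libraries. Per the labels, the lungs were flash frozen, RNA was extracted with a Zymo Direct-zol kit, and libraries followed Illumina protocols. The oxygen concentration, the length of exposure, the mouse strain, litters, batches and the time of day of harvest were not used here, since the labels state none of them. The labels also do not say that the libraries come from separate animals, so every p-value measures the spread between these samples.

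The deposited table holds FPKM values (fragments scaled to transcript length and to the number of mapped fragments) on a linear scale. The unit is inferred from the tools the authors name, TopHat2 2.0 and Cufflinks 2.0 with the mm10 genome build, and from the values themselves. The restriction to coding genes and the quantile normalization, which gives every library nearly the same set of ranked values, are read from the name of the file and were checked on its values. In 56.4% of ranks all 22 libraries held the same value within 1% of the mean, or of 1 where the mean was lower. This share includes ranks at 0 in every library, which agree trivially, since each library held at least 5327 genes at 0. Library sums ran from 529406 to 533090. The sequencing depth is therefore unknown, and no counting error, interval or floor is given. The highest value, 20504.1, is shared, and Sftpc sits at or near it in most libraries, so a rise of Sftpc cannot be seen. The table holds 22520 genes, of which 21740 (96.5%) have an identifier in the GENCODE M21 annotation (GRCm38, mm10), and 124 symbols are used by more than 1 gene. Coordinates are from that annotation. All 22 columns were used.

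All group comparisons were fitted with limma 3.58.1 in R 4.3.3. Values were transformed as log2(value + 1), genes with a value of at least 1 in at least 2 libraries were kept (14200), and 1 linear model without intercept was fitted to the 8 groups, with empirical Bayes moderation and an intensity trend. Fold changes on this scale understate the change of genes near or below a value of 1. There were 14 contrasts. Hyperoxia was compared with room air in each sex at each day, and as the mean of both sexes at each day. Interaction contrasts tested whether the oxygen effect differed between the sexes at each day or between the days. Females were compared with males in each of the 4 conditions, and PND21 with PND7 in room air. These tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Errors are given as SE for log2 fold changes and as SD for group means. Median fold changes over all genes were within 0.03 of 0 on the log2 scale in every contrast.

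The 36 gene lists cover p53 targets, Nrf2 targets, other antioxidant enzymes, the cell cycle, angiogenesis, pan-endothelial markers, alveolar type 2, alveolar type 1, transitional alveolar epithelial, club and ciliated cells, smooth muscle and myofibroblasts, matrix and elastic fibres, lipofibroblasts and alveolar fibroblasts, alveolar macrophages, monocytes and interstitial macrophages, neutrophils, T and NK cells, B cells, mast cells, erythroid cells, cardiac muscle, skeletal muscle, thymocytes, adipose tissue, interferon-stimulated genes, inflammatory cytokines and NF-kB, TGF-beta and BMP responses, hypoxia, glucocorticoid response, the circadian clock, immediate early genes, cholesterol synthesis, oxidative phosphorylation, Y-linked genes and X-linked genes that escape inactivation. Each list was tested with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists of a contrast. Lists with at least 4 tested members were used, which leaves 35, since thymocyte markers had 3. List members were also counted with p-values adjusted over the list alone. Overlap of male and female calls was tested with Fisher's exact test, one-sided for more overlap. This test takes genes as independent, which they are not, so its p-values are too low.

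Genes are named by a rule. It takes, in each contrast, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 2 in 1 of the groups and no overlap between the libraries of the groups (not applied to interactions), up to 4 members of each list with the lowest adjusted p, and a fixed set made of Cdkn1a, Vegfa, Kdr, Flt1, Mki67, Col1a1, Eln, Acta2, Sftpc, Nqo1, Cyp1a1, Cyp1a2, Cyp1b1, Ddx3y, Eif2s3y, Kdm5d, Uty and Xist. Xist is not among the coding genes of the table, and Cyp1a2 did not pass the filter on low values. Some genes that the rule selects are not reported here. The groups, contrasts, tests, lists, naming rule and the first 11 alternatives below were chosen before the data were examined. These alternatives were a pseudocount of 0.1, no filter, a stricter filter (mean of at least 5), median-ratio rescaling, robust empirical Bayes, library quality weights, a fold change of at least 1.5, a fit on the groups of a contrast only, leaving out each library in turn, an estimated correlation for list tests, and an overlap at an adjusted p under 0.1. Leaving out 6 libraries rich in skeletal muscle transcripts, and adding the mean log2 value of the skeletal muscle list (the muscle score) as a covariate, were chosen after seeing the data. So was a term for the block of sample numbers in the library titles at PND21 (3 to 9 or 10 to 15), since the labels do not say what these numbers stand for. A higher minimum of the muscle score, which left out 5 libraries, was also added then.

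The procedure was tested on simulated data in which 200 genes were changed by 1.5, 2 or 4-fold. Noise was drawn independently for each gene and library, without the differences between whole libraries that the real data hold. The rates below therefore do not cover such differences. In the male PND7 contrast it recovered 43.3%, 82.1% and 95.5% of them, with 9.26% false calls. In the sex-averaged PND7 contrast it recovered 74.6%, 94.0% and 97.0%. In the interaction of sex and oxygen at PND7 it recovered 17.9%, 62.7% and 86.4%.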

Results

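The data are gene-level FPKM values for 22 mouse lung libraries, 11 from males and 11 from females, 11 from room air and 11 from hyperoxia. At PND7 there were 2 male room air, 3 male hyperoxia, 3 female room air and 2 female hyperoxia libraries. At PND21 each of the 4 groups held 3 libraries. The title of the series names neonatal hyperoxic lung injury and differences between the sexes, so the comparisons ask what hyperoxia changed at each day and whether males and females responded differently. Depth is unknown because the values are quantile normalized. At PND7 the sample numbers in the library titles ran from 17 to 23 in room air and from 26 to 33 in hyperoxia. Anything tied to that order cannot be told apart from oxygen there, which also enters the comparison of the oxygen effect between the days. All PND21 libraries had lower numbers, so that order cannot be told apart from age either. At PND21 both oxygen groups were spread over numbers 3 to 9 (4 room air, 2 hyperoxia) and 10 to 15 (2 room air, 4 hyperoxia). All 11 male libraries held Ddx3y, a Y-linked RNA helicase, at 12.1 or more, and all 11 female libraries at 0.102 or less, so the sex labels matched the values.

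The first principal component carried 48.7% of the variance and parted PND7 from PND21. The second carried 18.5% and set apart 6 libraries that were rich in skeletal muscle transcripts. Mylpf, a fast skeletal muscle myosin light chain, stood at 74.2 to 772 in these 6 and at no more than 17.7 in the other libraries. Krt13, a keratin of stratified squamous epithelium, stood at 140 to 1534 against at most 35.9. The 6 were Male_RA_PND7 replicate 2, Female_RA_PND7 replicate 2, Male_HO_PND7 replicate 1, Female_HO_PND7 replicate 2, Male_RA_PND21 replicate 1 and Female_RA_PND21 replicate 1, that is 4 from room air and 2 from hyperoxia. Within groups, the first component carried 47.4% of the remaining variance and was led by Krt13, Krt4, Tnnc2, Krtdap and Mylpf.

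**Figure D1:**
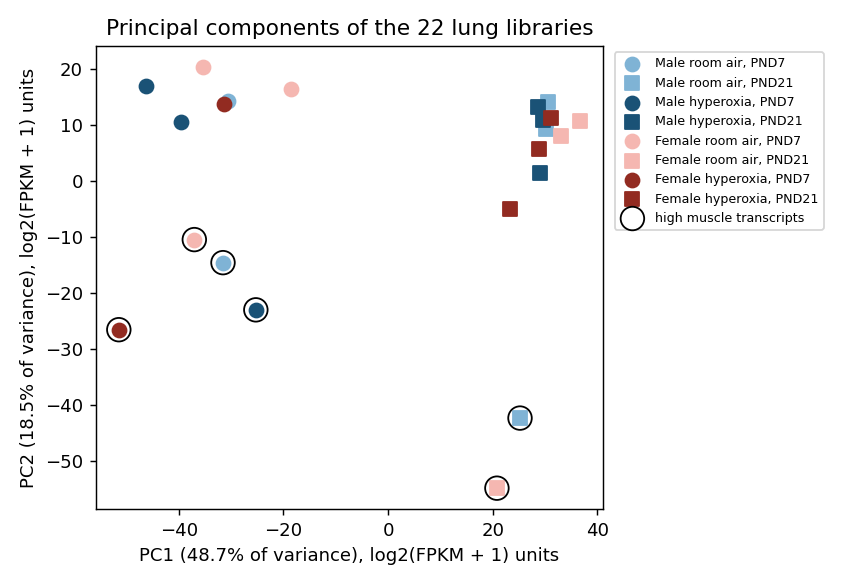
Principal components of the log2(value + 1) table, with 1 point per library (22), coloured by group. The first axis (48.7% of variance) parts the days, and the 6 ringed libraries at the negative end of the second axis (18.5%) are those rich in skeletal muscle transcripts.

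In male lungs at PND7, hyperoxia raised mast cell proteases and macrophage markers, and lowered elastin and other matrix genes. Cma1, mast cell chymase (ENSMUSG00000022225, chromosome 14, 55941451 to 55944675), averaged 25.5 ± 7.08 (SD, n = 3) in hyperoxia and 3.89 ± 0.265 (SD, n = 2) in room air, a log2 fold change of 2.41 (SE 0.34, adjusted p = 0.000744). Cpa3, mast cell carboxypeptidase (ENSMUSG00000001865, chromosome 3, 20215620 to 20242181), rose from 2.41 ± 0.661 to 16.3 ± 5.23. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), rose from 25.7 ± 6.57 to 50.3 ± 3.61 (log2 fold change 0.96, SE 0.23, adjusted p = 0.0170). Eln, which encodes elastin (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323), fell from 1561 ± 38.2 to 632 ± 99.8 (log2 fold change -1.32, SE 0.25, adjusted p = 0.00513).

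The other large rises in males were Saa3, an acute phase protein (log2 fold change 3.43, SE 0.86), Spp1, osteopontin (3.10, SE 0.53), the chemokines Cxcl17 (2.42) and Ccl9 (2.30), the mast cell protease Mcpt2 (2.05) and Lrg1 (2.02). Saa3 varied widely in hyperoxia, at 51.0 ± 49.4 against 2.51 ± 0.481. The largest falls were Crabp1, a retinoic acid binding protein (-2.32, SE 0.44), Mup3 (-2.26), Fabp1 (-2.17), Ccdc3 (-1.71), Trim67 (-1.49), Slitrk6 (-1.48), Adcy8 (-1.48) and Enpp1 (-1.47). Ccdc3 averaged 4.84 ± 1.35 in hyperoxia and 17.9 ± 1.79 in room air. Mcpt2, Saa3 and Mup3 belong to families of similar genes, between which reads can be shared. In all, 1240 of 14200 genes were called, 478 higher and 762 lower, with 3658 at an unadjusted p under 0.05 where 710 are expected by chance. Of the higher genes 59 changed by at least 2-fold, and of the lower genes 63.

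Of 6 mast cell markers in males 5 rose (5 adjusted over the list alone; adjusted p = 9.36e-06, and adjusted p = 0.170 with an estimated correlation). Of 12 monocyte and interstitial macrophage markers 7 rose, among them the complement genes C1qa (log2 fold change 1.03) and C1qb (1.07) and the lysosomal marker Cd68 (1.09). Adjusted over the list alone 9 rose (adjusted p = 1.43e-06, and adjusted p = 0.261 with an estimated correlation). Of 25 matrix and elastic fibre genes 11 fell, including Eln, Col3a1 (-0.94) and Tnc (-1.11), while Timp1, an inhibitor of matrix metalloproteinases, rose (1.05). Adjusted over the list alone 12 fell and 1 rose (adjusted p = 3.01e-06, and adjusted p = 0.375 with an estimated correlation). Of 12 smooth muscle and myofibroblast markers 3 fell, namely Tgfbi (-1.28), Pdgfra (-1.28) and Aspn (-1.09), with 5 adjusted over the list alone. Of 26 angiogenesis genes 8 fell, among them the receptor Tek (-0.89) and its ligand Angpt1 (-0.42), and 1 rose; adjusted over the list alone 12 fell and 3 rose. Of 19 Nrf2 targets 4 rose, such as Hmox1 (0.56) and Prdx1 (0.43), and of 30 cell cycle genes 3 rose, such as Ccnb2 (0.92), against 5 and 10 adjusted over the list alone. Vegfa (-0.35), Kdr (-0.31), Mki67 (0.31), Col1a1 (-0.67), Acta2 (-0.38) and Nqo1 (0.61) did not pass. The skeletal muscle list had a median log2 fold change of -1.0 with 0 of 9 members called by limma and 0 at an unadjusted p under 0.05.

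The male count rested on the 2 room air libraries, since it was 143 without Male_RA_PND7 replicate 1 and 151 without replicate 2; it was 730 and 627 without Male_HO_PND7 replicates 2 and 3, 283 without the 6 muscle-rich libraries and 5532 with library quality weights. Of the 18 called genes named by size or in the fixed set, 7 kept their call without each library in turn, while Saa3, Spp1, Cxcl17, Ccl9, Lrg1, Crabp1, Mup3, Fabp1, Slitrk6, Cdkn1a and Eln lost it without a room air replicate, and Saa3 and Cxcl17 also without Male_HO_PND7 replicate 1. Cdkn1a stood at 0.71 without Male_RA_PND7 replicate 1, and Eln at -1.29 and -1.34 without replicates 1 and 2.

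In female lungs at PND7, hyperoxia also raised mast cell proteases, macrophage markers and Cdkn1a, and lowered B cell markers and single mesenchymal genes such as Pdgfra (log2 fold change -1.39). Cma1 averaged 31.7 ± 10.3 (SD, n = 2) in hyperoxia and 3.66 ± 1.09 (SD, n = 3) in room air, a log2 fold change of 2.80 (SE 0.34, adjusted p = 0.000208). Cpa3 averaged 19.3 ± 7.58 against 2.42 ± 0.210, and the tryptase Tpsb2 18.7 ± 3.33 against 3.83 ± 0.330. Mcpt2 averaged 3.75 ± 1.40 in hyperoxia and was listed at 0 in all 3 room air libraries. Cdkn1a rose from 21.8 ± 1.47 to 52.1 ± 7.67 (log2 fold change 1.21, SE 0.23, adjusted p = 0.00543). Agt, which encodes angiotensinogen (ENSMUSG00000031980, chromosome 8, 124556534 to 124569706), fell from 92.3 ± 19.8 to 26.6 ± 2.80 (log2 fold change -1.74, SE 0.19, adjusted p = 0.000143).

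The other large rises in females were Saa3 (log2 fold change 3.01), Spp1 (2.40), Gm20418 (2.34) and the interferon-stimulated Oas1g (2.06). The other large falls were the immediate early transcription factor Egr1 (-2.24), Acoxl (-2.14), Ccdc3 (-2.03), Adcy8 (-1.76), the phosphatase Dusp1 (-1.71), the Wnt inhibitor Wif1 (-1.69) and Egfem1 (-1.66). Here 825 genes were called, 264 higher and 561 lower, with 3372 at an unadjusted p under 0.05. Of the higher genes 73 changed by at least 2-fold, and of the lower genes 60. Of 6 mast cell markers 5 rose and Gata2, a transcription factor that endothelial cells also express, fell (adjusted p = 8.43e-06, and adjusted p = 0.209 with an estimated correlation). Of 12 monocyte and interstitial macrophage markers 8 rose, with C1qa at 1.36 and C1qc at 1.40, and 11 adjusted over the list alone (adjusted p = 3e-10, and adjusted p = 0.209 with an estimated correlation). Of 9 B cell markers 4 fell, including Cd79a (-1.39) and Ms4a1 (-1.19), and 7 adjusted over the list alone (adjusted p = 1.47e-05, and adjusted p = 0.322 with an estimated correlation). Of 26 angiogenesis genes 5 fell, such as Angpt1 (-0.71), and 1, Apln (0.74), rose, with 11 and 1 adjusted over the list alone. Of 12 pan-endothelial markers 3 fell, such as Tmem100 (-1.02), and 6 adjusted over the list alone (adjusted p = 0.00166, and adjusted p = 0.450 with an estimated correlation). Of 12 smooth muscle and myofibroblast markers Pdgfra, Tgfbi (-1.18) and Aspn (-1.25) fell, also adjusted over the list alone, while the list had a median of 0.04 (adjusted p = 0.435). Of 25 matrix and elastic fibre genes 2 rose and 1 fell (adjusted p = 0.993). None of 30 cell cycle genes passed over all genes, and 21 rose adjusted over the list alone, with a median log2 fold change of 0.73 (adjusted p = 3.9e-11, and adjusted p = 0.388 with an estimated correlation). Eln (-0.56, adjusted p = 0.182), Vegfa (-0.49), Kdr (-0.28), Mki67 (0.67), Col1a1 (0.30), Acta2 (0.45) and Nqo1 (0.32) did not pass. The skeletal muscle list had a median log2 fold change of 1.47, with 0 of 9 members called by limma and 0 at an unadjusted p under 0.05.

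Of 16 interferon-stimulated genes 6 rose in females, and 13 adjusted over the list alone (adjusted p = 4.03e-09, and adjusted p = 0.322 with an estimated correlation), but 1 library carried this: Isg15 read 91.7 in Female_HO_PND7 replicate 1 and 10.6 in replicate 2, and without replicate 1 the median of the list was 0.12 with 0 called. Without Female_RA_PND7 replicates 2 or 3 it also had 0 called, without Female_RA_PND7 replicate 1 it had 1, and without Female_HO_PND7 replicate 2 it had 15. The female count was 265 without Female_RA_PND7 replicate 3, 313 and 400 without Female_HO_PND7 replicates 1 and 2, and 0 by limma with only the 2 groups in the fit (2562 at an unadjusted p under 0.05); Saa3, Gm20418, Spp1, Oas1g, Egr1, Dusp1 and Cdkn1a each lost their call without 1 of the libraries, Cdkn1a (1.07) without Female_HO_PND7 replicate 2.

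The male and female responses at PND7 went the same way. Both sexes called 419 genes in the same direction, 138 higher and 281 lower, and 0 in opposite directions. Of independent lists 72.0 are expected (Fisher's exact test, one-sided, p = 9.18e-241). Genes that move together or vary little can raise the overlap above this number, so the p-value overstates the evidence. Of the 1240 male calls 1195 had the same sign in females, and of the 825 female calls 808 had the same sign in males. Across genes, which are not independent replicates, the fold changes of the sexes correlated with a Pearson r of 0.593 and a Spearman rho of 0.617. In both sexes hyperoxia held the higher sample numbers, so anything tied to that order can raise the overlap and the correlation. The test of a different response in the sexes called 0 genes by limma, with 561 at an unadjusted p under 0.05. By list, 24 of 25 matrix and elastic fibre genes had a positive interaction, that is a lesser fall or a rise in females, with a median of 0.44 (adjusted p = 7.6e-11, and adjusted p = 0.60 with an estimated correlation). Interferon-stimulated genes had a median of 0.88 (adjusted p = 1.7e-06, and adjusted p = 0.77 with an estimated correlation). That median follows 1 library, since the list mean was 4.45 in Female_HO_PND7 replicate 1 and 2.32 in replicate 2. Immediate early genes had a median of -0.66 (adjusted p = 0.00027, and adjusted p = 0.65 with an estimated correlation). The skeletal muscle list moved with these, at a median of 2.72 (adjusted p = 0.024, and adjusted p = 0.83 with an estimated correlation). The interaction count was 37 without Female_HO_PND7 replicate 2, 1 without Male_RA_PND7 replicate 2, and 56 without the 6 muscle-rich libraries, a fit in which Male_RA_PND7 and Female_HO_PND7 hold 1 library each.

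Averaged over the sexes, hyperoxia at PND7 changed 3328 genes (23.4% of those tested), 1390 higher and 1938 lower. The mast cell proteases Cma1 (log2 fold change 2.60, SE 0.24, adjusted p = 3.12e-06) and Cpa3 (2.42, SE 0.21, adjusted p = 2.59e-06) rose in each sex, as did Saa3 (3.22), Spp1 (2.75), Mcpt2 (2.13) and Ccl9 (1.99). Cxcl17 (2.08) passed in males alone, and the protease inhibitor Slpi (1.95) in neither sex on its own. Cdkn1a rose by 1.09 (SE 0.16, adjusted p = 0.000244) and Eln fell by 0.94 (SE 0.18, adjusted p = 0.00153). Pdgfra, the platelet-derived growth factor receptor of alveolar fibroblasts and myofibroblasts, fell from 25.6 ± 0.322 to 10.1 ± 2.07 in males and from 25.7 ± 1.30 to 9.22 ± 1.21 in females. The largest falls were Ccdc3 (-1.87), Acoxl (-1.73), Fabp1 (-1.70), Adcy8 (-1.62), Agt (-1.59), Egfem1 (-1.55), Glp1r (-1.47) and Wif1 (-1.44).

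Immune genes moved in both directions. Of 12 monocyte and interstitial macrophage markers 11 rose, also adjusted over the list alone, with C1qa at 43.3 ± 8.50 against 20.4 ± 0.351 in males and 52.7 ± 17.6 against 19.5 ± 2.84 in females (list adjusted p = 1.03e-08, and adjusted p = 0.219 with an estimated correlation). Of 6 mast cell markers 5 rose and Gata2 fell, with a median log2 fold change of 1.60 (adjusted p = 2.46e-05, and adjusted p = 0.212 with an estimated correlation). The 5 that rose are all proteases. The list held 8 genes, of which Fcer1a and Ms4a2 did not pass the filter on low values. Of 11 alveolar macrophage markers 5 rose, such as the scavenger receptor Marco (1.62), and 1, Fabp1, fell, with 7 and 1 adjusted over the list alone (adjusted p = 0.0247, and adjusted p = 0.501 with an estimated correlation). Of 12 neutrophil markers 3 rose, including Lcn2 (1.60) and S100a8 (1.28), and 6 adjusted over the list alone (adjusted p = 0.0115, and adjusted p = 0.501 with an estimated correlation). Of 13 inflammatory cytokine and NF-kB genes 5 rose, led by the monocyte chemoattractant Ccl2 (1.47, SE 0.19), and 6 adjusted over the list alone (adjusted p = 0.000505, and adjusted p = 0.343 with an estimated correlation). Of 16 interferon-stimulated genes 6 rose, 12 adjusted over the list alone (adjusted p = 2.46e-05, and adjusted p = 0.405 with an estimated correlation), a count that was 1 without Male_RA_PND7 replicate 2 and 15 without Female_HO_PND7 replicate 2. Female_HO_PND7 replicate 1 had a list mean of 4.45, against at most 2.86 in the other PND7 libraries. B cell markers went the other way. Of 9, 6 fell, 7 adjusted over the list alone, with Cd79a at 5.05 ± 0.568 against 11.4 ± 0.958 in males and 4.34 ± 0.275 against 13.4 ± 4.04 in females (adjusted p = 0.000391, and adjusted p = 0.405 with an estimated correlation). Of 14 T and NK cell markers 1, Cd2 (-0.56), fell, and 0 adjusted over the list alone.

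Cell cycle genes rose. Of 30, 20 rose, 26 adjusted over the list alone and all 30 had a positive log2 fold change, with a median of 0.62 (adjusted p = 7.55e-11, and adjusted p = 0.405 with an estimated correlation). The mitotic cyclin Ccnb2 averaged 42.3 ± 14.2 against 21.4 ± 5.61 in males and 45.2 ± 7.0 against 27.1 ± 6.09 in females, and Mki67, a marker of cycling cells, rose by 0.49 (SE 0.17, adjusted p = 0.0436). The count of 20 was 7 without Male_RA_PND7 replicate 2, Female_HO_PND7 replicate 2 or all 6 muscle-rich libraries, and 13 without Male_HO_PND7 replicate 3 or Female_RA_PND7 replicate 3. Among 20 p53 targets 7 rose, including Cdkn1a, Gdf15 (0.68) and the proapoptotic Bax (0.31), and 2, Plk2 (-0.91) and Trp53inp1 (-0.44), fell, with 9 and 2 adjusted over the list alone (adjusted p = 0.0816). Of 19 Nrf2 targets 7 rose, among them the haem oxygenase Hmox1 (0.46, SE 0.08) and Prdx1 (0.36), with 8 higher and 1 lower adjusted over the list alone (adjusted p = 0.000394, and adjusted p = 0.279 with an estimated correlation). Of 15 other antioxidant enzymes 6 rose, led by the glutathione peroxidases Gpx1 (0.60, SE 0.05) and Gpx3 (0.86), and catalase, Cat, fell (-0.36), with 7 and 1 adjusted over the list alone (adjusted p = 0.000621, and adjusted p = 0.188 with an estimated correlation).

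Of 26 angiogenesis genes 14 fell, among them Angpt1 (log2 fold change -0.56, SE 0.07), Efnb2 (-0.82), Tek (-0.92) and Vegfa (-0.42, SE 0.12, adjusted p = 0.0159). Apln, the apelin ligand, was 1 of 2 that rose (0.74), and adjusted over the list alone 17 fell and 3 rose (adjusted p = 9.17e-05, and adjusted p = 0.405 with an estimated correlation). Kdr (-0.29) and Flt1 (-0.27), the receptors of Vegfa, did not pass. Of 12 pan-endothelial markers 8 fell, also adjusted over the list alone, such as Tmem100 (-0.91) and the cadherin Cdh5 (-0.52) (adjusted p = 0.000929, and adjusted p = 0.405 with an estimated correlation). Of 25 matrix and elastic fibre genes 9 fell, including Eln, Mfap2 (-0.67), Tnc (-0.83) and Col3a1 (-0.66), and 2, Timp1 (1.09) and the cross-linking enzyme Lox (0.33), rose, with 11 and 2 adjusted over the list alone (adjusted p = 0.00812, and adjusted p = 0.577 with an estimated correlation). Of 12 smooth muscle and myofibroblast markers 4 fell, also adjusted over the list alone, namely Tgfbi (-1.23), Pdgfra (-1.33), Aspn (-1.17) and Synpo2 (-0.42) (adjusted p = 0.0336, and adjusted p = 0.405 with an estimated correlation). Acta2, smooth muscle actin, did not pass (0.04). Of 11 lipofibroblast and alveolar fibroblast markers 4 fell, such as Npnt (-0.79) and the growth factor Fgf10 (-0.38), with 4 lower and 1 higher adjusted over the list alone. Without the 6 muscle-rich libraries the falls numbered 7 of 26 in angiogenesis, 2 of 12 in pan-endothelial and 6 of 25 in matrix genes.

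Of 12 alveolar type 2 markers 2 rose, Sftpd (0.55) and Sftpa1 (0.54), of 10 alveolar type 1 markers 1, Pdpn (0.29), and of 10 transitional markers 2, Itgb6 (0.35) and Lgals3 (0.64), against 2, 1 and 3 adjusted over the list alone. Of 8 club cell markers 3 rose, with Scgb3a2 at 1.11, also adjusted over the list alone, and 0 of 12 ciliated markers passed by limma. Slc2a1 (0.69) and Ldha (0.29) rose among 16 hypoxia-inducible genes, with 1 adjusted over the list alone. Of 12 glucocorticoid-responsive genes Fkbp5 rose (0.75) and Sgk1 fell (-0.53). Of 14 clock genes 3 fell, also adjusted over the list alone, namely Hlf (-1.37, SE 0.12), Tef (-0.31) and Clock (-0.21) (adjusted p = 0.0316, and adjusted p = 0.279 with an estimated correlation). Of 14 TGF-beta and BMP responsive genes 3 rose and 2 fell (4 and 3 adjusted over the list alone), of 12 immediate early genes Junb rose and 2, Nr4a1 (-1.42) and Jun (-0.31), fell, and of 14 cholesterol synthesis genes 1 fell. The erythroid, cardiac muscle, skeletal muscle, adipose, oxidative phosphorylation and Y-linked lists had 0 called members by limma and 0 adjusted over the list alone, and of 4 X-linked genes that escape inactivation 2, Kdm6a (-0.35) and Ddx3x (-0.25), fell. The skeletal muscle median was 0.05. Over all contrasts the median, the mean and the test direction of a list differed in sign in 52 of 490 list tests, and 0 of these had an adjusted p under 0.05 by camera. The sex-averaged count was 2060 and 1914 without Male_RA_PND7 replicates 1 and 2, 2057 without Female_HO_PND7 replicate 2 and 1684 without the 6 muscle-rich libraries. Of 20 called genes named by size or in the fixed set, Mki67, Slpi and Vegfa lost their call without 1 library and the other 17 kept it, and Mki67 and Vegfa lost it without the 6 muscle-rich libraries.

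**Figure D2:**
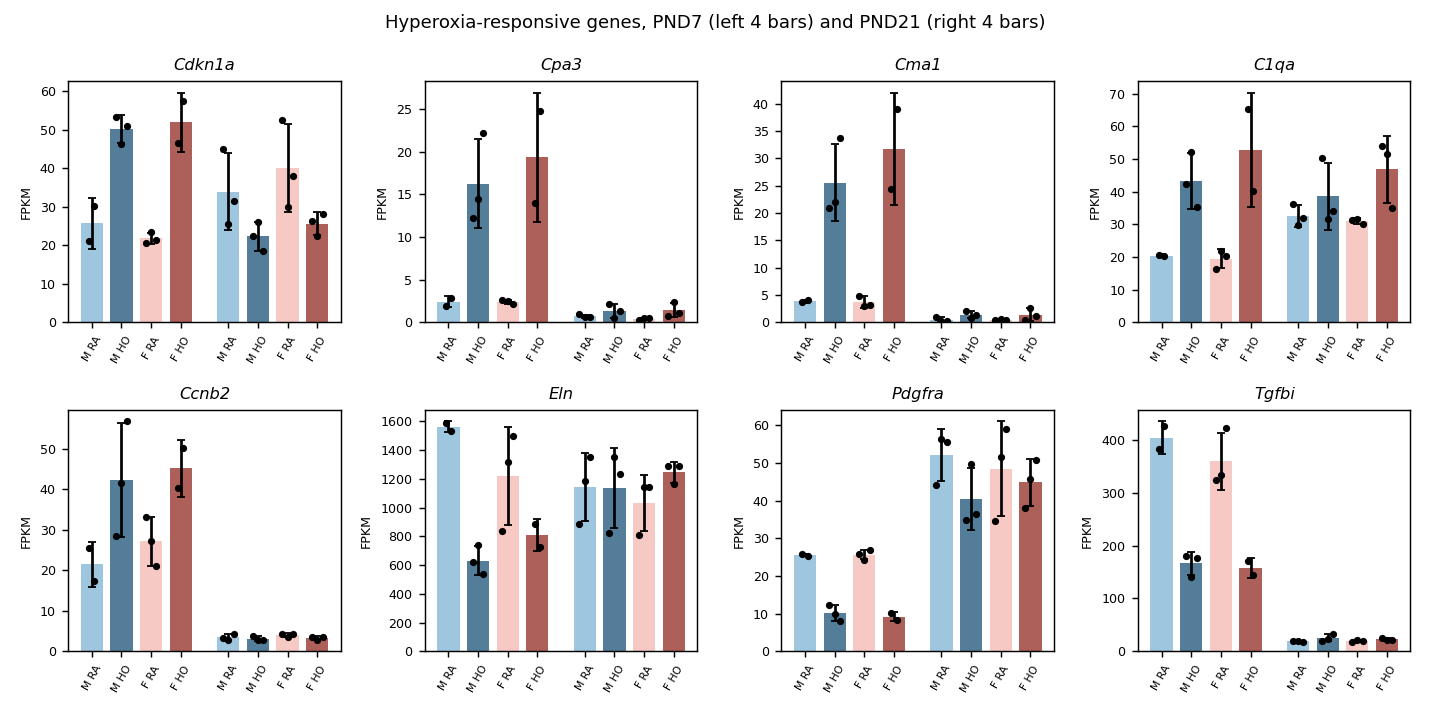
FPKM of 8 genes in the 8 groups, with PND7 on the left and PND21 on the right of each panel; bars are means, error bars SD (n = 2 or 3) and points single libraries. At PND7 Cdkn1a, Cpa3, Cma1, C1qa and Ccnb2 stood higher in hyperoxia, and Eln, Pdgfra and Tgfbi lower, as with Cma1 at 25.5 against 3.89 in males.

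**Figure D3:**
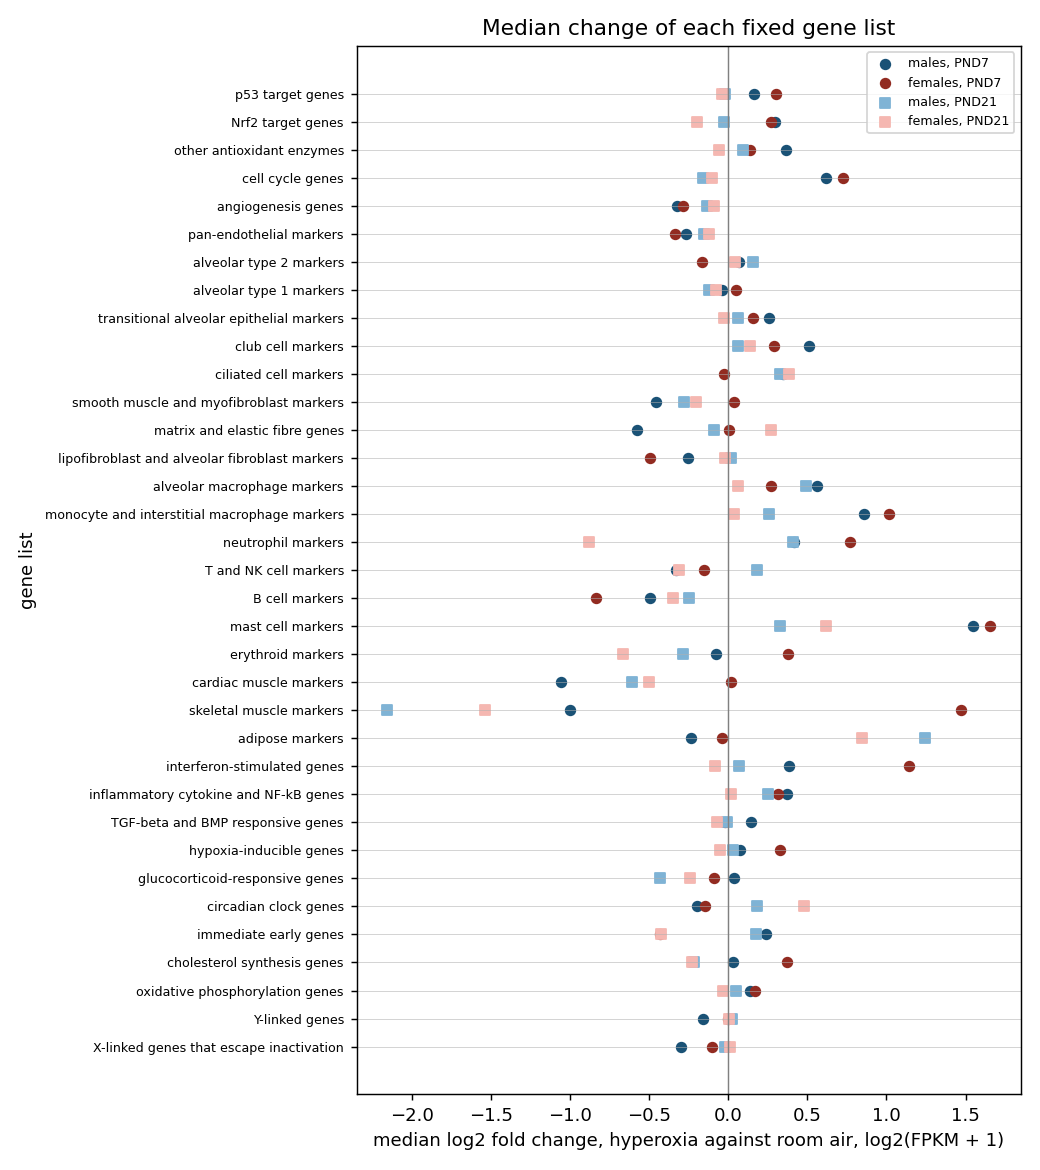
Median log2 fold change, hyperoxia against room air, of the 35 tested gene lists in males and females at PND7 and PND21. At PND7 the mast cell list lies at 1.55 in males and 1.66 in females, while the skeletal muscle list points in opposite directions in the sexes (-1.0 and 1.47).

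In male lungs at PND21, 3 genes were called by limma. Unc119, a lipid-binding trafficking protein (ENSMUSG00000002058, chromosome 11, 78343482 to 78349164), rose from 16.5 ± 0.327 to 23.0 ± 0.532 (SD, n = 3 per group; log2 fold change 0.45, SE 0.06, adjusted p = 0.0101). Colq, the collagen tail of acetylcholinesterase (ENSMUSG00000057606, chromosome 14, 31523082 to 31591343), fell from 16.1 ± 0.834 to 8.0 ± 1.25 (-0.93, SE 0.14, adjusted p = 0.0373). Spon2, a secreted matrix protein (ENSMUSG00000037379, chromosome 5, 33198184 to 33218455), fell from 36.8 ± 2.55 to 23.6 ± 2.68 (-0.62, SE 0.10, adjusted p = 0.0373). At an unadjusted p under 0.05 there were 994 genes. Of 14 clock genes 0 passed over all genes, and 4 rose adjusted over the list alone, with a median of 0.18 (adjusted p = 0.0446, and adjusted p = 0.649 with an estimated correlation). The count was 0 without any of Male_RA_PND21 replicates 1, 2 and 3 or Male_HO_PND21 replicates 2 and 3, 1 without the 6 muscle-rich libraries and 309 with library quality weights.

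In female lungs at PND21, clock genes stood higher in hyperoxia and a pair of retinoid genes lower. The labels give no time of harvest, so a difference in it cannot be told apart from an effect of hyperoxia on the clock genes. Per2, a repressor of the circadian clock (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324), averaged 8.59 ± 0.931 in hyperoxia and 4.21 ± 0.463 in room air (SD, n = 3 per group; log2 fold change 0.88, SE 0.09, adjusted p = 0.000538). Dbp, a clock-driven transcription factor (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), rose from 9.0 ± 1.61 to 25.6 ± 3.30 (1.42, SE 0.24, adjusted p = 0.0234). Per3 (1.14), Nr1d2 (0.81) and Tef (0.63) rose as well. Cyp26b1, which degrades retinoic acid (ENSMUSG00000063415, chromosome 6, 84571414 to 84593908), fell from 17.1 ± 2.67 to 5.02 ± 0.958 (-1.59, SE 0.22, adjusted p = 0.00426). Lrat, which esterifies retinol for storage (ENSMUSG00000028003, chromosome 3, 82892579 to 82903973), fell from 12.7 ± 3.97 to 3.86 ± 1.07 (-1.48, SE 0.19, adjusted p = 0.0022). Colq (-0.97) and Spon2 (-0.64) completed the 9 called genes, with 1367 at an unadjusted p under 0.05. Of 14 clock genes 5 rose, with 8 higher and 1 lower adjusted over the list alone (adjusted p = 2.17e-07, and adjusted p = 0.00575 with an estimated correlation). The count was 25 and 30 without Female_RA_PND21 replicate 1 and Female_HO_PND21 replicate 3, and 3 to 5 without each of the other 4 libraries, where Per2, Tef and Lrat kept their calls. Without the 6 muscle-rich libraries Dbp, Nr1d2, Cyp26b1, Colq and Spon2 lost theirs, and with only the 2 groups in the fit limma called 0 genes (1058 at an unadjusted p under 0.05), against 4007 with library quality weights.

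Averaged over the sexes at PND21, 40 genes were called, 24 higher and 16 lower, with 1640 at an unadjusted p under 0.05. Clock genes rose, namely Dbp (log2 fold change 1.11, SE 0.17, adjusted p = 0.00734), Per3 (0.85), Nr1d2 (0.53), Hlf (0.51), Tef (0.49, SE 0.06) and Per2 (0.43). These 6 of 14 clock genes rose over all genes and 8 rose and 2 fell adjusted over the list alone (adjusted p = 1.01e-05, and adjusted p = 0.0221 with an estimated correlation). Aspn, a proteoglycan of the matrix, rose from 26.2 ± 3.80 to 57.3 ± 18.3 in males and from 25.8 ± 4.07 to 53.9 ± 22.7 in females (1.02, SE 0.16, adjusted p = 0.00747). Pigr, the epithelial transporter of secretory antibodies (1.44, SE 0.24), the iron exporter Slc40a1 (0.64) and Camk1g (0.59) also rose. Cyp1a1, an enzyme induced through the aryl hydrocarbon receptor (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824), averaged 0.0797 ± 0.0418 against 8.84 ± 12.4 in males and 0.205 ± 0.216 against 8.70 ± 3.27 in females (-2.63, SE 0.41, adjusted p = 0.00734). Igfbp3 (-0.98), Colq (-0.95), Lrat (-1.05), Wisp2 (-0.87), Nrn1 (-0.74), Neurl3 (-0.67) and Spon2 (-0.63) fell. Cdkn1a did not pass (-0.58, adjusted p = 0.102).

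Besides the clock list, Aspn among 12 smooth muscle and myofibroblast markers and Id2 (0.49) among 14 TGF-beta and BMP responsive genes were the called list members at PND21. All 14 cholesterol synthesis genes had negative log2 fold changes, with a median of -0.23, 0 called by limma and 3 lower adjusted over the list alone (adjusted p = 2.24e-06, and adjusted p = 0.573 with an estimated correlation). Erythroid (-0.47), B cell (-0.32) and skeletal muscle (-1.81) medians were negative and ciliated (0.37) and adipose (1.17) medians positive, each with an adjusted p of 0.00267 or less and adjusted p = 0.573 with an estimated correlation. The adipose median rested on single libraries, with Adipoq at 39.2 in Male_HO_PND21 replicate 1 and 30.2 in Female_HO_PND21 replicate 2 and at most 4.25 in the others of that day. The skeletal muscle median moved with the room air groups, which hold both muscle-rich libraries of PND21. The count of 40 was 22 without Male_RA_PND21 replicate 1, Male_HO_PND21 replicate 3 or Female_RA_PND21 replicate 2, 26 without Female_RA_PND21 replicate 3, 18 without Female_HO_PND21 replicate 1, 117 and 93 without Female_RA_PND21 replicate 1 and Female_HO_PND21 replicate 3, 70 without the 6 muscle-rich libraries and 2557 with library quality weights. With the block of sample numbers (3 to 9 or 10 to 15) as a term it was 74, of which 34 were among the 40, and the 6 clock genes stayed called. Without the 6 muscle-rich libraries Aspn, Pigr, Camk1g, Nrn1 and Hlf (0.34) lost their calls. Of 16 called genes named by size or in the fixed set, 6 lost their call without single libraries. Among them were Nrn1, Camk1g, Nr1d2, Neurl3 and Igfbp3. Between 4 and 6 clock genes were called without each library of that day in turn.

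**Figure D4:**
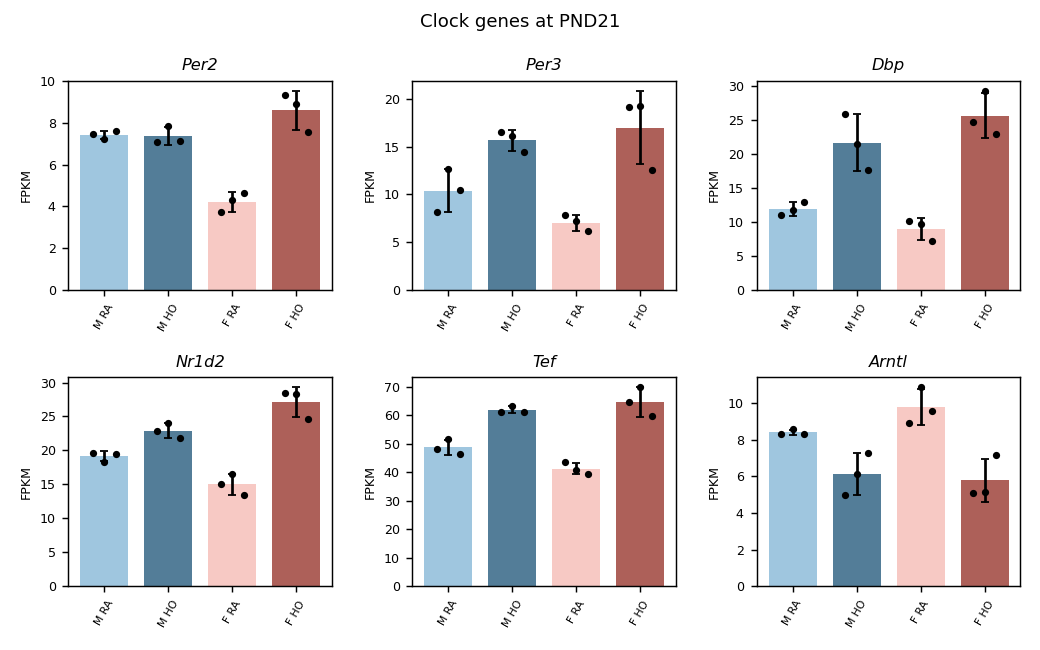
FPKM of 6 clock genes at PND21 in the 4 groups of 3 libraries; bars are means, error bars SD and points libraries. Per2 stands at 8.59 in female hyperoxia against 4.21 in female room air and at 7.36 against 7.42 in males, while Arntl, which did not pass, reads lower in hyperoxia.

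The response differed between the sexes at PND21 for 2 genes. Per2 rose in females and not in males (7.36 ± 0.442 against 7.42 ± 0.205), an interaction of 0.89 (SE 0.13, adjusted p = 0.0293). Unc119 rose in males and averaged 20.1 ± 0.763 against 21.8 ± 1.35 in females, an interaction of -0.56 (SE 0.08, adjusted p = 0.0293). Of the 4 groups, Per2 was lowest in female room air and Unc119 in male room air. Both genes were also called between the sexes in room air. A shift of those room air groups cannot be told apart from a response that differs between the sexes. At an unadjusted p under 0.05 there were 665 genes, fewer than the 710 expected by chance. The clock list had a median interaction of 0.32 (adjusted p = 0.00012, and adjusted p = 0.072 with an estimated correlation). Of the 3 male and 9 female calls 2 were shared, Colq and Spon2, where 0.00190 are expected (Fisher's exact test, one-sided, p = 1.07e-06). The fold changes correlated across genes with r = 0.546 and rho = 0.306. In both sexes hyperoxia held more of the libraries numbered 10 to 15, and room air held the muscle-rich ones. These shared differences can raise the overlap and the correlation without an effect of oxygen. The interaction count was 0 or 1 without 10 of the 12 libraries of that day in turn, all except Male_HO_PND21 replicate 2 and Female_HO_PND21 replicate 3, and 0 by limma without the 6 muscle-rich libraries (817 at an unadjusted p under 0.05). It was 931 with library quality weights, and 2, the same genes, with the block of sample numbers as a term.

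The response to hyperoxia differed between the days for 1498 genes, 1006 with a higher and 492 with a lower effect at PND21, and 3959 at an unadjusted p under 0.05. Cdkn1a rose at PND7 and not at PND21, a difference of -1.66 (SE 0.21, adjusted p = 0.000234). Eln fell at PND7 and stood at 1136 ± 278 against 1141 ± 236 in males and 1246 ± 72.8 against 1032 ± 195 in females at PND21 (difference 1.07, SE 0.24, adjusted p = 0.0102). Aspn fell at PND7 and rose at PND21 (2.19, SE 0.24, adjusted p = 5.64e-05), and the clock output factor Hlf did so too (1.88, adjusted p = 6.76e-06). Egfem1 (2.18), Ccdc3 (2.0), Crabp1 (1.93), Ptpn5 (1.87), Cacna1g (1.77) and Wif1 (1.71) had the other largest positive differences. Spp1 (-3.18, adjusted p = 0.00133), Slpi (-2.78, adjusted p = 0.0489), Gm20418 (-2.43), Cyp1a1 (-2.33), Mcpt2 (-2.08), Cma1 (-1.95), Cpa3 (-1.86) and Ifi27l2a (-1.82) had the largest negative ones. Of 30 cell cycle genes 11 had a lower effect at PND21, and 27 adjusted over the list alone (adjusted p = 4.99e-13, and adjusted p = 0.483 with an estimated correlation). So had 6 of 12 monocyte and interstitial macrophage markers (10 adjusted over the list alone, adjusted p = 7.69e-06, and adjusted p = 0.280 with an estimated correlation) and 4 of 6 mast cell markers (5 adjusted over the list alone, adjusted p = 9.3e-05, and adjusted p = 0.130 with an estimated correlation). With a pseudocount of 0.1 only 1 mast cell marker was called, at a list median of -1.07 against -1.05. Of 14 clock genes 6 had a higher effect at PND21, and 8 adjusted over the list alone (adjusted p = 0.000117, and adjusted p = 0.0776 with an estimated correlation). Of the 1390 genes higher at PND7 3 were also higher at PND21 (2.35 expected of independent lists), and of the 1938 lower 5 were also lower (2.18 expected). In opposite directions, 6 genes were lower at PND7 and higher at PND21 (3.28 expected), and 1 was higher and then lower (1.57 expected). The count was 826 and 811 without Male_RA_PND7 replicates 1 and 2, 994 without Female_HO_PND7 replicate 2, 983 without Male_RA_PND21 replicate 1, 991 without Male_HO_PND21 replicate 2 and 697 without the 6 muscle-rich libraries, which left 1 cell cycle gene called at a median of -0.74 against -0.79 in all libraries. Interferon-stimulated genes went from 1 of 16 with a lower effect (median -0.75) to 12 without the 6 (median -1.22). The count was 3969 with library quality weights and 2456 with the block of sample numbers as a term. The skeletal muscle list moved with these changes at a median of -1.86, which was 0.18 without the 6 libraries, and the adipose list at 1.37, with 0 members of either called by limma and 0 adjusted over the list alone. Slpi, Gm20418, Cyp1a1, Nqo1 and Ifi27l2a lost their calls without single libraries, and Crabp1, Eln and Slpi without the 6.

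Between females and males 5 to 9 genes were called in each of the 4 comparisons, most of them on the sex chromosomes. With library quality weights the counts at PND21 were 101 in room air and 1086 in hyperoxia. The Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were lower in females in all 4 comparisons; Ddx3y differed by -3.94 in room air at PND7 (SE 0.11, adjusted p = 9.02e-14), and the Y list held with an estimated correlation (adjusted p = 1.01e-07 or less). Eif2s3x, an X-linked gene that escapes inactivation, was higher in females in all 4, at 46.9 ± 2.82 (SD, n = 3) against 30.2 ± 1.40 (SD, n = 2) in room air at PND7. Of 4 such genes 1 was higher at PND7 and 2 at PND21 in either oxygen condition, and 4 adjusted over the list alone (adjusted p = 3.46e-05 or less with an estimated correlation). In room air at PND7 the sixth of 6 called genes was Mup3, a major urinary protein gene, at 0.136 ± 0.0658 in females and 4.37 ± 2.44 in males (-2.16, SE 0.36, adjusted p = 0.0280). In hyperoxia at PND7 the 5 called genes were Eif2s3x and the 4 Y-linked genes. In room air at PND21 9 genes were called, among them Per2, at 4.21 ± 0.463 in females and 7.42 ± 0.205 in males (-0.70, SE 0.09, adjusted p = 0.00237), Unc119 (0.38), Kdm6a (0.66) and I830077J02Rik (0.81). The clock list had a median of -0.21 there (adjusted p = 0.000208, and adjusted p = 0.0276 with an estimated correlation). In hyperoxia at PND21 9 genes were called, among them the glucocorticoid-responsive transcription factor Zbtb16, at 9.78 ± 2.87 in females and 2.34 ± 1.92 in males (1.80, SE 0.31, adjusted p = 0.0383), and Cyp26b1, at 5.02 ± 0.958 and 13.7 ± 2.21 (-1.29, SE 0.22, adjusted p = 0.0344). Unadjusted p-values under 0.05 numbered 328, 320, 451 and 757 in the 4 comparisons. The count in hyperoxia at PND7 was 62 without Female_HO_PND7 replicate 2, and that in hyperoxia at PND21 was 5 without Male_HO_PND21 replicate 1 or 3; Mup3, Unc119, I830077J02Rik, Kdm6a, Zbtb16 and Cyp26b1 lost their calls without single libraries, Zbtb16 also with the block of sample numbers as a term (1.80), and Per2 in room air at PND21 and Eif2s3x in hyperoxia at PND7 without the 6 muscle-rich ones.

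In room air, lungs differed widely between PND7 and PND21, with 7019 genes called (49.4%), 3354 higher and 3665 lower. Sample numbers ran from 17 to 23 at PND7 and from 3 to 13 at PND21, so anything tied to that order cannot be told apart from age. Tgfbi, a matrix adhesion protein (ENSMUSG00000035493, chromosome 13, 56609523 to 56639562), went from 404 ± 30.9 (SD, n = 2) to 18.6 ± 1.76 (SD, n = 3) in males and from 360 ± 54.0 to 19.6 ± 2.27 in females (log2 fold change -4.25, SE 0.12, adjusted p = 5.49e-14). Cxcl14, a chemokine (ENSMUSG00000021508, chromosome 13, 56288643 to 56296551), went from 3.98 ± 0.653 to 112 ± 18.1 in males and from 3.42 ± 0.50 to 107 ± 24.1 in females (4.54, SE 0.13, adjusted p = 1.12e-13). Inmt (6.17), Serpina3n (4.40), the macrophage gene Chi3l3 (4.26), 9230104L09Rik (3.38), Lrat (3.15), Colq (3.12) and Gpx3 (3.0) had the other largest rises, and the fetal growth gene Dlk1 (-5.14), Prss35 (-4.89), Egfem1 (-4.26), Agt (-4.07), Tnc (-3.46), Slc27a6 (-3.40) and Mdk (-3.26) the other largest falls. All 30 cell cycle genes fell, with a median of -1.87 (adjusted p = 2.39e-17, and adjusted p = 0.516 with an estimated correlation). Of 25 matrix and elastic fibre genes 17 fell and 1 rose, such as Tnc and Loxl2 (-1.87), with 19 and 1 adjusted over the list alone. Of 12 smooth muscle and myofibroblast markers 7 fell and 1 rose, with Acta2 at -1.81. All 14 T and NK cell markers rose (median 0.92), all 9 B cell markers rose (median 1.75; adjusted p = 5.34e-07, and adjusted p = 0.423 with an estimated correlation), and 14 of 16 interferon-stimulated genes rose. Of 10 alveolar type 1 markers 7 rose, such as Hopx (1.11), and of 12 alveolar type 2 markers 5 rose, such as Sftpa1 (1.20), and 1 fell, the saturated Sftpc. Of 6 mast cell markers 4 fell, with Cma1 at -1.69, and Gata2 rose (0.92). Of 12 glucocorticoid-responsive genes 7 rose and 1 fell, with Klf9 at 2.15 and Tsc22d3 at 1.72, and of 15 other antioxidant enzymes 9 rose and 1 fell, with the extracellular superoxide dismutase Sod3 at 2.5. Of the list tests in this contrast 0 were called by camera with an estimated correlation. Of 26 called genes named by size or in the fixed set, Nqo1 and Ddx3y lost their call without single libraries.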

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

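The tests of explanations in this part, other than the counts over splits of all libraries, were chosen after the results were seen. The results here are those for which a test showed a difference between the sexes or the days in the effect of hyperoxia.

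At PND21 the effect of hyperoxia differed between females and males in 2 genes, Per2 (interaction 0.89) and Unc119 (-0.56), each with adjusted p = 0.0293. Per2 was lowest in female room air and Unc119 in male room air, and both were called between the sexes in room air. A shift of those room air groups cannot be told apart from a response that differs between the sexes. Other splits of the 12 libraries gave at most 1 gene, and the real split was the 1 of 100 with as many. A margin of 1 gene does not exclude chance for these 2 genes. With the block of sample numbers (3 to 9 or 10 to 15) as a term 2 genes were again called, and 1 of 72 splits within blocks called as many (highest other 1). Neither gene kept its call without every single library in turn or without the 6 muscle-rich libraries, where limma called 0 genes (817 at an unadjusted p under 0.05). For Unc119 no technical explanation was tested beyond that block and the muscle-rich libraries.

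The clock genes at PND21 are the first pattern weighed. Of 6 called clock genes 5 stayed called with the muscle score as a covariate. All 6 stayed called with the block of sample numbers as a term. These fits argue against carried-along tissue that holds muscle, and against that block, as the whole cause. Other tissue is not covered by them. The highest adipose list means of that day were in Male_HO_PND21 replicate 1 and Female_HO_PND21 replicate 2, and no fit adjusted for adipose tissue. With the covariate the sixth, Hlf, had a log2 fold change of 0.51 (SE 0.10) before and 0.43 (SE 0.09) after, so that its call, close to the threshold at first, ended with a slightly lower fold. Per, Dbp, Nr1d and Tef genes lay above Arntl, Npas2 and Clock by a difference of medians of 0.86 (0.49 in males and 1.31 in females), which is what another time of day at harvest could give. A difference in harvest time and an effect of hyperoxia on the clock cannot be told apart here, since the labels give no time of harvest.

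Between the days, the effect of hyperoxia differed in 1498 genes. Other splits gave at most 693, and 1 of 100, the real one, gave as many. These splits exchanged oxygen labels within each sex and day, so they stand for no oxygen effect at either day. They cannot decide whether the effect differed between the days. Higher effects at PND21 were those of Aspn (2.19), Egfem1 (2.18), Ccdc3 (2.0), Crabp1 (1.93), Hlf (1.88), Ptpn5 (1.87), Cacna1g (1.77) and Wif1 (1.71). Lower effects were those of Spp1 (-3.18), Slpi (-2.78), Gm20418 (-2.43), Cyp1a1 (-2.33), Mcpt2 (-2.08), Cma1 (-1.95), Cpa3 (-1.86) and Ifi27l2a (-1.82). The Cyp1a1 difference rested on room air libraries at PND21, which averaged 8.84 ± 12.4 in males and 8.70 ± 3.27 in females.

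The mast cell proteases, higher in hyperoxia at PND7, are the second pattern weighed. With the muscle score as a covariate the median log2 fold change of the mast cell list was 1.60 and without the 6 muscle-rich libraries 1.64. The muscle-rich libraries of PND7 lay in both oxygen groups, so the covariate could hardly move this median. The rise among the libraries without the muscle signal argues against carried-along tissue that holds muscle. Other tissue is not covered by these fits. A lower share of the main cell types would raise other minor cell types alike. The B cell list had a median of -0.56 with 6 of 9 members lower, while monocyte, macrophage and neutrophil markers rose. The B cell list was chosen after its fall was seen. A lower share of the main cell types together with a separate loss of B cells thus stays open. Reads shared between protease paralogs would not raise Cpa3, a carboxypeptidase outside the chymase and tryptase families, which rose by 2.42. More mast cells, or more protease RNA in each, remain open: of other genes that mast cells express, chosen after the values were seen, Il1rl1 rose by 0.48 (adjusted p = 0.0103), Kit fell by 1.33 (adjusted p = 1.25e-05), and Hdc (-0.31), Hpgds (0.24) and Srgn (0.09) did not pass. The members of the mast cell list that rose were all proteases, and its members Fcer1a and Ms4a2 were too low to be tested.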

How the results depend on the processing

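Leaving out the 6 muscle-rich libraries, the muscle score minimum of 3, the muscle score covariate and the block of sample numbers at PND21 as a term were chosen after seeing the data. The other alternatives were planned. No value of a named gene that was called reversed under any alternative, and among 495 called values of named genes 479 kept direction and call with a pseudocount of 0.1, 488 with rescaling, 486 with robust moderation, 485 with the covariate, and 348 without the 6 libraries. With only the groups of the contrast in the fit, which was not run for the day by oxygen interaction because it uses every group, 265 did so and 157 lost their call. No paired analysis was possible because replicate numbers are not said to link libraries. Depth limits could not be given, since depth is unknown. Where a group was left with 1 library, it was assumed to vary like the others. The cause was not tested for the changed counts below, except that a fold minimum can only lower a count by construction.

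Leaving out each library in turn gave, for hyperoxia at PND7, 143 to 1244 genes in males, 265 to 749 in females and 1914 to 3712 for the mean of the sexes. At PND21 it gave 0 to 3 in males, 3 to 30 in females and 18 to 117 for the mean. The sex by oxygen interaction gave 0 to 37 at PND7 and 0 to 2 at PND21, and the day by oxygen interaction 811 to 2042. Females against males gave 5 to 7 and 5 to 62 in room air and hyperoxia at PND7, and 6 to 9 and 5 to 10 at PND21. The age contrast gave 5954 to 7303.

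With no filter, males at PND21 had 1 gene, the sex interaction 3 at PND7 and 1 at PND21, and females against males in hyperoxia at PND7 9. The stricter filter gave 25 for the mean at PND21, and for females against males 3 in room air and 3 in hyperoxia at PND7 and 5 in hyperoxia at PND21. Rescaling gave 7 in males at PND21. Quality weights gave 5532 in males and 5063 for the mean at PND7, 309 in males, 4007 in females and 2557 for the mean at PND21, 931 for the sex interaction at PND21, 3969 for the day interaction, and 101 and 1086 for females against males at PND21 in room air and hyperoxia. A fold of at least 1.5 gave 565, 472 and 715 in males, females and the mean at PND7, 16 for the mean at PND21, 1 for the sex interaction at PND21, 638 for the day interaction and 2521 for age.

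With only the groups of the contrast in the fit, males at PND7 had 158, and limma called 0 in females at PND7 (2562 at an unadjusted p under 0.05), 0 in males at PND21 (1243) and 0 in females at PND21 (1058); females against males gave 3 in room air at PND7, and 4 in room air and 4 in hyperoxia at PND21. Without the 6 libraries the counts were 283, 513 and 1684 in males, females and the mean at PND7, 1 in males and 70 for the mean at PND21, 56 and 0 for the sex interaction at PND7 and PND21 (817 at an unadjusted p under 0.05 by limma in the latter), 697 for the day interaction, and 30, 51 and 5 for females against males in room air at PND7, hyperoxia at PND7 and room air at PND21. With a muscle score minimum of 3, which leaves out 5 libraries, the limma counts were 263, 380 and 1327 in males, females and the mean at PND7, 0 (911 at an unadjusted p under 0.05), 9 and 37 at PND21, 50 and 0 (704) for the sex interaction at PND7 and PND21, 472 for the day interaction, 17, 64, 5 and 7 for females against males, and 5737 for age. The covariate gave 2035 in males at PND7, and 9 in males and 66 for the mean at PND21. The block term gave 74 for the mean at PND21 and 2456 for the day interaction, and of the called values of named genes in contrasts with PND21 libraries 252 kept direction and call and 4 lost their call.

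With an estimated correlation, camera called 0 lists in males, females and the mean at PND7, in males at PND21, in the 3 interactions and in the age contrast, 1 in females and 1 in the mean at PND21, and 2, 2, 3 and 2 in females against males. The covariate gave 11 lists and the block term 10 in males at PND21, and without the 6 libraries 6 were called in the sex interaction at PND7 and 9 in females against males in hyperoxia at PND7. The overlap of the sexes at PND7 was 853 at an adjusted p under 0.1 and 125 without the 6 libraries, and that at PND21 was 0 without the 6.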

Other observations

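The tests of explanations in this part were chosen after the results were seen, as were the splits within blocks, and the other counts over splits of the libraries before. The 6 muscle-rich libraries also held transcripts of stratified squamous epithelium. Krt4, a keratin of that epithelium, stood at 108 to 1012 in these 6 and at most 22.6 in the other 16, and Krt5 at 17.3 to 212 against at most 4.76. The muscle enzyme Ckm stood at 21.9 to 444 against at most 12.8. The mean log2 value of 10 squamous genes was 4.16 to 7.42 against at most 2.53, and the skeletal muscle score 3.0 to 6.82 against at most 2.14. Both of these maxima were in Female_HO_PND21 replicate 1, and the remaining libraries had at most 0.83 and 1.15. That hyperoxia library thus carried a weaker form of the signal.

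The source of these transcripts is the third pattern weighed. For 6 of 10 further striated muscle genes the same 6 libraries were the highest, a bound of more than 5 set after the values were seen. Hyperoxia as the cause is argued against by the room air libraries, of which 4 of 11 carried the signal. A candidate source is a piece of oesophagus carried along at dissection, since in the mouse it holds both striated muscle and a squamous lining, but other muscle and epithelium near the lung stay open.

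Whether hyperoxia moves the lung along its change with age was tested across genes, which are not independent replicates. Because both contrasts share the room air libraries, these were split between them. At PND7 the correlation had a median of -0.00305 over 12 splits (-0.104 to 0.168). At PND21 the median was -0.133 over 36 splits (-0.291 to 0.146). Both ranges include 0, so whether hyperoxia moves the lung along or against its change with age stays open at both days.

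Other splits of the libraries were counted for contrasts with at least 3 libraries on each side, with the sexes counted together where a contrast averages them. For the mean of the sexes at PND7 the real split called 3328 genes and the highest other 2083, and 1 of 100 splits called as many, so chance can be excluded. For the mean at PND21, 40 genes were called, and 4 of 100 splits, drawn from 200, called as many. The highest other, 1292, parted the libraries numbered 10 to 15 in their titles from those numbered 3 to 9, which points to a structure of the samples other than oxygen, and a term for this block called 842 genes. In block 10 to 15, numbers 11 and 13 were muscle-rich, and 10 and 15 had the highest adipose list means. Number 14 had the next highest muscle score, and 12 had neither signal. This block and tissue carried along can thus not be fully told apart. With the block as a term 74 genes were called, and of the 81 splits within blocks 1, the real one, called as many (highest other 2). No other split within blocks came near the real count. The block was chosen after the splits of all libraries had pointed to it, so this count does not exclude chance. For age, 7019 genes were called against 5470 in the highest other split, and 1 of 100 called as many, so chance can be excluded. An effect tied to the order of sample numbers, which parts the days, cannot. With 10 splits, too few for a share under 0.05, hyperoxia in males at PND21 called 3 genes (highest other 0, 1 split with as many), and in females 9 (highest other 1277, which follows the same blocks, 2 splits with as many). Females against males at PND21 called 9 in room air (highest other 0, 1 split with as many) and 9 in hyperoxia (highest other 1, 1 split with as many).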
